A study of Bos grunniens and Bos grunniens x Bos taurus and Bos taurus with 9 samples.

How the data were processed

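Single-cell RNA was measured in 9 lung libraries, from 3 yaks, 3 dzho (hybrids of yak and cattle) and 3 cattle. Per the labels' protocols, tissue from 6 sites of each lung was pooled per animal, kept frozen in freezing medium, minced, digested with enzymes and strained, and red cells were lysed. Sampling kept away from bronchi and vessels as far as possible, per the same protocols. The labels give no altitude, batch, sex or age, and groups and replicate numbers were taken from the sample titles. Replicates are separate animals per the labels.

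The deposited files hold raw UMI counts per gene and cell barcode for 35676 genes, and they were used as deposited. Per the submitters' processing notes, the authors made these counts with Cell Ranger 5.0.0 on the cattle genome build ARS-UCD1.2, so reads of yak and dzho were also counted on the cattle genome. Each library held between 7998 and 15349 barcodes and between 29939974 and 62368406 UMIs. No genome of that build was used here, so no coordinates are given, and gene names are those of the files.

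Cells with at least 300 genes, at least 500 UMIs and under 20% mitochondrial UMIs were kept, which left 89592 of 94898 barcodes. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold marked under 0.5% of cells in 8 of the 9 libraries, so the cells scoring above the quantile for an expected share of 0.8% per 1000 cells were left out of the named classes and sums. This marked 7149 cells (7.98%). No pair of libraries agreed within sampling noise, and each was counted as its own sample.

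Counts were scaled per cell and log transformed, and 40 principal components were computed from 2500 variable genes without the mitochondrial ones. Neighbours (scikit-learn 1.9.0) were drawn 4 per library, so that every library entered each cell's neighbourhood, and weighted with umap-learn 0.5.12. Leiden clustering (igraph 0.11.9, resolution 1) gave 30 clusters. A cluster was called X-like from marker lists fixed before the data were examined. The markers' mean log2 fold over all other cells had to reach 1, at least 3 markers had to exceed a 2-fold difference, at least 1 marker had to be among the 10 leading genes or at least 90% of the markers over a 2-fold difference, no other class was to have as many markers, and the majority of its cells were not to be predicted doublets. Folds were computed after adding 10 CPM. The scoring rule, unlike the markers, was set on these data. In all, 19 clusters received 15 class names (49492 cells). The remaining 11 clusters (32951 cells) stayed unnamed, and held 53.6% of yak, 37.3% of dzho and 31.2% of cattle cells. Endothelial-like cells were clustered again on their own (2000 genes, 20 components, resolution 0.6).

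UMI counts were summed per library and class. The 12 classes with at least 25 cells in each of the 9 libraries were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, a robust quasi-likelihood fit of all 9 libraries together, and Benjamini-Hochberg adjustment over the genes of a class at a threshold of 0.05. Levels are CPM of the summed UMIs of a library and class. Gene lists, also fixed then, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, in 5 classes and for lists of at least 5 tested members, with adjustment over all 105 tests. The lists of red cell and platelet transcripts had too few tested members in each of these 5 classes. Class shares were tested with exact permutation tests over all 1680 assignments of the 9 libraries to 3 groups of 3, 1-sided by construction, and pairs of groups with exact 2-sided permutation tests, which cannot go below p = 0.1.

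The genes named in the text followed a rule fixed then too. For yak against cattle these are the largest increases and decreases past the threshold (5 each way in endothelial-like cells, 3 in the other main classes, 1 elsewhere) with a mean of at least 20 CPM, no overlap between the groups' libraries, and a class level of at least 0.1 of the gene's highest class. For the other comparisons the rule takes the 2 largest each way, in endothelial-like cells and in the class with the most calls. It adds up to 4 members per list and class by smallest p, and 12 endothelial genes whatever their result. Results of a few of these genes are not reported here, and their rows were left out of the tables of alternatives and of opposite directions, but not of any test or list count. A gene at under 0.1 of the level in its highest class is described as at the level of free RNA, since droplets also hold RNA released from other cells. A fold against a group with no UMI is a lower bound, computed against 3 counts over the group, and ratios with 1 to 3 counts in a group carry a 95% exact interval. Such bounds and intervals cover counting error only.

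The tests were tried on simulated counts with 200 changed genes and a raised glycolysis list. For yak against cattle in endothelial-like cells (9509 genes), 1.49% of simulated 1.5-fold, 19.4% of 2-fold and 74.2% of 4-fold changes were recovered. For 4-fold changes the recovered share was 83.3% in AT2-like (8637 genes), 80.3% in T cell-like (11096 genes), 50.0% in fibroblast-like (10466 genes) and 37.9% in macrophage-like cells (7655 genes). Between 3.23% and 8.33% of the simulated calls were unchanged genes.

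Alternatives fixed at the start were RLE scaling, DESeq2 1.42.0, no low-count filter, a replicate block, only the compared groups in the fit, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), doublets kept, an ordinary neighbour graph of 30 neighbours, genes at free RNA level left out, counts thinned to the smallest library of each class, and each library left out in turn. For the lists they were camera with an estimated correlation and fry, for shares the compartment as denominator, for the subtypes a lower and a higher resolution, and for the dzho position genes with at least a 2-fold difference. Ribosomal RNA genes left out, the ribosomal RNA share as a covariate, aerocyte-like cells alone, shares that include the unnamed clusters, thinning for the dzho position, and dzho 2 and cattle 2 left out together were chosen after seeing the data.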

Results

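The lungs of yak, of dzho, which are hybrids of yak and cattle, and of cattle were compared by single-cell RNA sequencing in a study of how yak are adapted to high altitude. There were 9 libraries, 3 animals per group. The filtered libraries held 27127 yak, 27773 dzho and 34692 cattle cells, and the median cell of a library had between 1132 (cattle 2) and 3492 (dzho 3) UMIs. Mitochondrial transcripts took 5.03% ± 0.494 of UMIs in yak, 4.28% ± 0.315 in dzho and 4.68% ± 0.505 in cattle (SD, n = 3 animals each; exact permutation p = 0.2). RN18S1, the 18S ribosomal RNA, took 9.19% ± 1.88 of UMIs in yak and 8.72% ± 4.69 in dzho but 0.549% ± 0.251 in cattle (exact permutation p = 0.0357). Dzho 2 had the lowest share of the dzho at 3.84%. XIST, the RNA that coats the inactive X chromosome of female cells, had between 19412 and 28158 UMIs in each cattle library and at most 3 in any yak or dzho library (exact permutation p = 0.0179).

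To ask whether the lungs differed in cell makeup, the share of each class among named cells was compared. T cell-like cells made up 40.3% ± 4.39 of named cells in yak, 26.4% (13.5% to 37.2%) in dzho and 12.5% ± 3.70 in cattle (exact permutation p = 0.0179, adjusted p = 0.125, SD, n = 3). Smooth muscle-like cells, which form the muscle of airways and vessels, were at 0.339% ± 0.309, 1.11% ± 1.39 and 4.48% ± 1.25 (exact p = 0.025, adjusted p = 0.125). Secretory-like cells of the airway lining were at 1.24% ± 0.433, 2.47% ± 0.967 and 4.29% ± 1.97 (exact p = 0.0393, adjusted p = 0.147). Neutrophil-like cells were rare, at 0.408% ± 0.109, 0.113% ± 0.0633 and 0.163% ± 0.103 (exact p = 0.0179, adjusted p = 0.125). Endothelial-like cells were at 7.78% ± 1.84 in yak, 16.2% ± 15.5 in dzho and 24.8% ± 4.14 in cattle (exact p = 0.168), with 33.8% in dzho 2 alone. B cell-like cells were at 16.7% ± 8.19, 12.4% ± 5.26 and 4.32% ± 1.36 (exact p = 0.1) and fibroblast-like cells at 5.06% ± 3.27, 6.28% ± 2.98 and 12.1% ± 5.04 (exact p = 0.136).

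The alveolar classes overlapped between groups. Surfactant-making AT2-like cells were at 2.95% ± 1.17, 3.68% ± 0.529 and 5.04% ± 1.95 in yak, dzho and cattle (exact p = 0.229). The flat AT1-like cells of the gas exchange surface were at 4.27% ± 2.68, 5.62% ± 3.41 and 6.30% ± 3.50 (exact p = 0.711). Macrophage-like cells were at 8.95% ± 3.78, 12.03% ± 5.63 and 14.4% ± 11.2 (exact p = 0.782). NK-like, plasma-like, lymphatic endothelial-like, ciliated-like and proliferating-like shares had exact p between 0.0643 and 0.45. None of the 15 classes passed the adjusted threshold in the exact permutation test, and 4 had an unadjusted p under 0.05. A class alone could not pass, since the smallest p this test can give stays above 0.05 after adjustment over 15 classes. The lack of a passing class is therefore no sign that the shares are alike. Shares depend on the freezing, digestion and straining of the tissue and on the 11 clusters that stayed unnamed, which held 53.6% of yak but 31.2% of cattle cells.

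**Figure D1:**
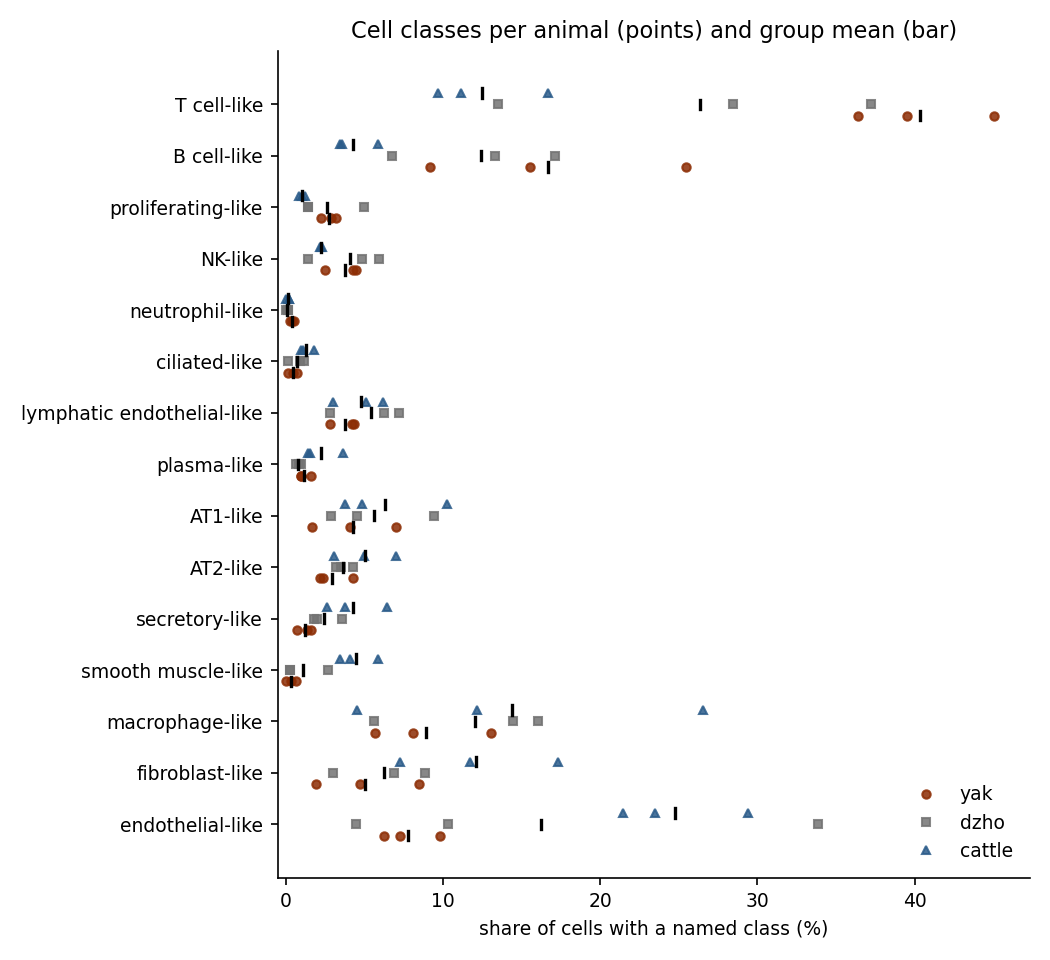
Share of each cell class among named cells (percent, horizontal axis), with the 3 animals of each group as points and their mean as a bar. T cell-like cells had means of 40.3%, 26.4% and 12.5% and endothelial-like cells 7.78%, 16.2% and 24.8%.

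Endothelial-like cells, which line the blood vessels, were clustered again on their own (913 yak, 2844 dzho and 5419 cattle cells). Aerocyte-like cells, the capillary cells that face the alveoli, made up 31.6% ± 6.73 of them in yak, 26.2% ± 6.95 in dzho and 12.9% ± 3.18 in cattle (exact permutation p = 0.025, adjusted p = 0.113, SD, n = 3). Arterial-like cells were at 7.06% ± 1.45, 4.52% ± 3.29 and 6.49% ± 2.92 (exact p = 0.514) and venous-like cells at 9.57% ± 0.595, 6.10% ± 7.59 and 10.8% ± 4.32 (exact p = 0.521). An unnamed endothelial cluster led by LYVE1, NTRK2 and RSPO3 was at 10.2% ± 1.40, 16.6% ± 2.94 and 24.8% ± 8.83 (exact p = 0.05, adjusted p = 0.15). No subtype passed the adjusted threshold in the exact permutation test (2 had p under 0.05), and 1 subtype did with the stricter cell filter or without cattle 2.

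Within endothelial-like cells, 2196 of 9509 genes differed between yak and cattle, 1049 higher and 1147 lower in yak (831 and 1529 with no low-count filter). FMO1, a flavin-containing monooxygenase, was at 1133 ± 483 CPM in yak, 660 ± 185 in dzho and 0.218 ± 0.239 in cattle (SD, n = 3). Its log2 fold change was 12.06 ± 0.67 (SE; edgeR adjusted p = 8.7e-07). Its relative FMO2 (141 ± 96.9 CPM in yak, 0.527 ± 0.543 in cattle), CCDC102B (6.85 ± 1.03), RN18S1 (4.98 ± 0.58) and the noncoding RNA TUNAR (4.47 ± 0.62) were the other largest increases by the naming rule, with edgeR adjusted p between 5.8e-04 and 0.0163. Among the largest decreases, IFI47, of a family of interferon-inducible GTPases, was at 1.39 ± 0.238 CPM in yak, 115 ± 7.57 in dzho and 243 ± 87.0 in cattle. This is a 177-fold ratio of CPM (95% counting interval 60.6 to 860; edgeR adjusted p = 2.9e-06). NTRK2, a receptor of neurotrophins, was 79.2-fold lower by the same ratio (27.1 to 384; log2 fold change -6.33 ± 1.08, adjusted p = 0.00741), and it also led the unnamed cluster with LYVE1 above. No UMI was found in yak for XIST (at least 352-fold lower), for the signalling adaptor STAP2 (at least 36.6-fold lower) or for SYT4 (at least 31.8-fold lower). Counts of 0 in yak, here and in other classes, would also arise where yak reads do not map to the cattle genome, which was not tested. TUNAR is also among the leading genes of the aerocyte-like cluster, and in aerocyte-like cells alone it missed the threshold (3.22, adjusted p = 0.0744).

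Single genes of vessel growth and vessel tone moved both ways. FLT1, a receptor of the growth factor VEGF, was at 353 ± 68.1 CPM in yak, 161 ± 9.91 in dzho and 92.4 ± 6.04 in cattle (log2 fold change 1.93 ± 0.23, adjusted p = 5.8e-04). EDNRB, an endothelin receptor that also marks aerocytes, was at 468 ± 179, 308 ± 156 and 88.0 ± 54.7 CPM (2.41 ± 0.58, adjusted p = 0.0191). ACE, which makes angiotensin II, was at 192 ± 68.5, 216.3 ± 32.9 and 75.0 ± 15.7 (1.36 ± 0.28, adjusted p = 0.00906). GUCY1A1, a subunit of the nitric oxide receptor, rose by 1.88 ± 0.27 and PTGS1, a prostaglandin synthase, by 2.31 ± 0.37. JAG1 rose by 1.41 ± 0.27 and ESM1 by 1.76 ± 0.38, while APLNR (-1.30 ± 0.33) and DDAH2 (-1.46 ± 0.29) fell. EPAS1, the hypoxia-inducible factor HIF-2α, was at 308 ± 91.3 CPM in yak, 392 ± 186 in dzho and 152 ± 44.2 in cattle, which missed the threshold (1.02 ± 0.36, adjusted p = 0.0587). HIF1A (0.03 ± 0.26, adjusted p = 0.942), EGLN1 (0.27 ± 0.22), KDR (0.78 ± 0.34) and NOS3 (0.42 ± 0.33) did not pass. Nor did EDN1 (1.03 ± 0.75), CA4 (-0.77 ± 0.68), VWF (-0.05 ± 0.71) and VEGFA (0.71 ± 0.43, at the level of free RNA). In aerocyte-like cells alone, which were 31.6% of these cells in yak and 12.9% in cattle, log2 fold changes were 1.25 for EDNRB, 1.09 for FLT1 and 1.02 for EPAS1 (adjusted p = 0.0369). They were 0.50 for ACE (adjusted p = 0.291) and -2.38 for NOS3 (adjusted p = 0.0402). ESM1 missed the threshold there (0.85, adjusted p = 0.119), while PTGS1 (4.88), JAG1 (1.78) and DDAH2 (-1.27) passed it. In aerocyte-like cells CA4 differed too (adjusted p = 0.0124) and had no UMI in yak. EDNRB missed the threshold without yak 1 (adjusted p = 0.0623), yak 3 (0.0735) or cattle 3 (0.0622) and with no low-count filter (0.0695), and FMO2 in 6 and SYT4 in 9 of the settings fixed at the start. EPAS1 passed without dzho 2 (adjusted p = 0.0434) or dzho 3 (0.026), with DESeq2 (0.0473) and with only yak and cattle in the fit (0.0286).

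**Figure D2:**
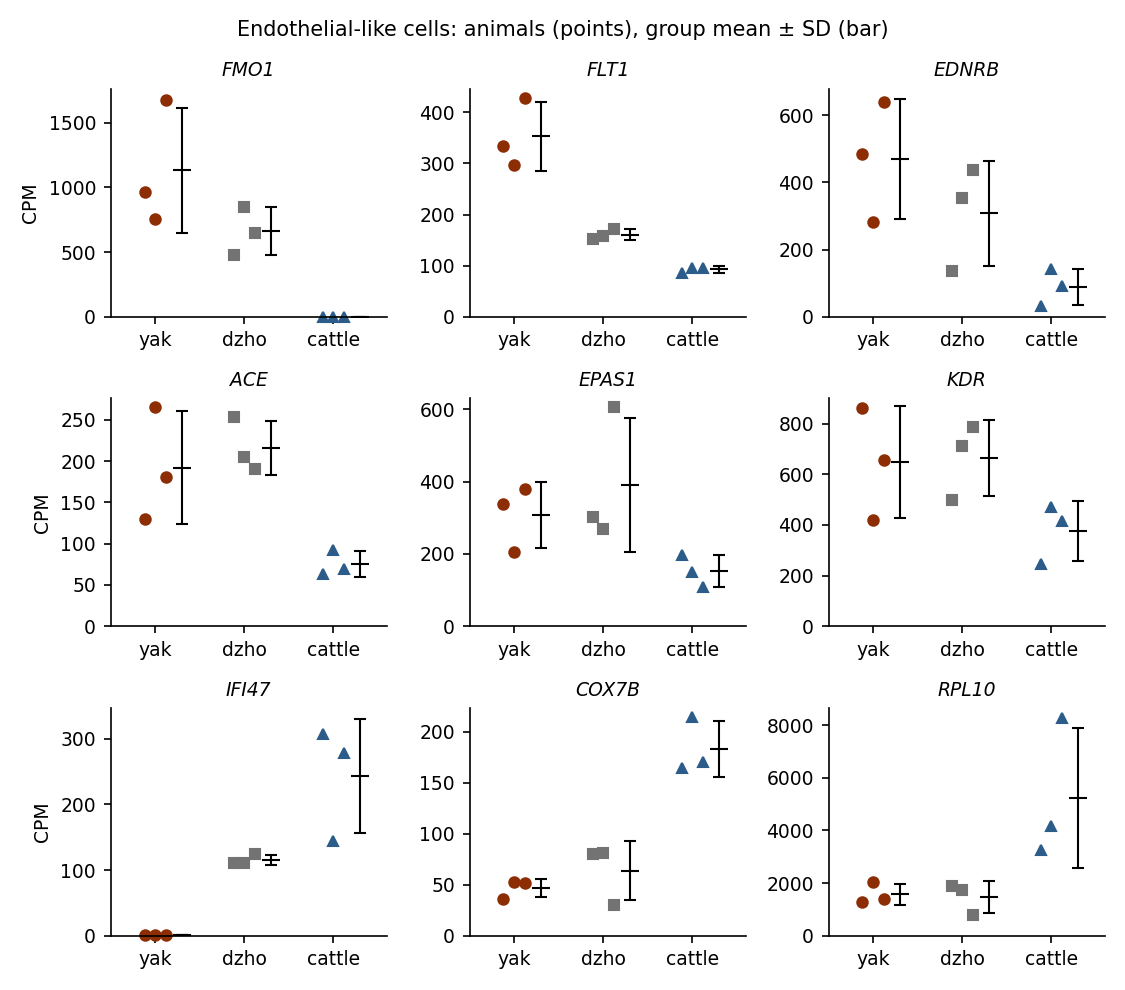
Level of named genes (CPM, vertical axis) in endothelial-like cells, with the 3 animals of each group as points and mean ± SD as a bar. FMO1 lay at 1133 CPM in yak and 0.218 in cattle on average, and FLT1 at 353 and 92.4.

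By the lists, 39 of 59 nuclear genes of oxidative phosphorylation, which makes ATP in mitochondria, were lower in yak endothelial-like cells and none were higher (52 adjusted over the list alone). Among them were COX7B (-1.96 ± 0.34), ATP5MC2 (-1.69 ± 0.33) and SDHB (-1.18 ± 0.25). Of 82 ribosomal protein genes 37 were lower (56 adjusted over the list alone), RPL15 most clearly by p (-3.62 ± 0.49). Of 27 antioxidant genes 8 fell (11 adjusted over the list alone, where 1 rose), including the peroxidases PRDX1 (-1.80 ± 0.34) and PRDX2 (-1.67 ± 0.32) and the dismutase SOD1 (-1.49 ± 0.32). Of 32 interferon response genes 5 fell (3 adjusted over the list alone), including IFI6 (-2.83 ± 0.64) and IFIT3 (-1.71 ± 0.40). Of 15 glycolysis genes LDHB, PGAM1 and PGK1 fell, and of 23 early response genes BTG2 and JUNB (3 and 2 adjusted over the list alone). These 6 lists passed camera as lower (adjusted p between 7.6e-15 and 0.0157), but each had adjusted p = 0.909 with an estimated correlation. Angiogenesis genes (6 higher, 2 lower of 33; adjusted p = 0.112) and vascular tone genes (5 higher, 3 lower of 23; adjusted p = 0.119) did not pass camera. By fry, a test also fixed at the start, the angiogenesis list passed as higher (adjusted p = 0.00174), alone of the lists in these cells, but with an estimated correlation it had adjusted p = 0.855. Adjusted over the list alone, 7 and 6 were higher. Of 34 hypoxia targets 4 were higher, including DDIT4 (1.91 ± 0.38) and KDM3A (1.19 ± 0.25), and 3 lower, including MIF (-2.41 ± 0.30), with adjusted p = 0.826. Of 16 HIF regulators CREBBP and EP300 were higher and 4 were lower, RBX1 and ELOB among them (adjusted p = 0.839). Adjusted over the list alone, 4 hypoxia targets were higher and 3 lower, and 4 HIF regulators were higher and 4 lower. In aerocyte-like cells alone SDHB, BTG2, PGK1, KDM3A and EP300 missed the threshold (edgeR adjusted p between 0.0594 and 0.37), with their direction kept. Past the threshold there were COX7B, ATP5MC2, RPL15, PRDX1, PRDX2, SOD1, IFI6, LDHB, PGAM1, JUNB, DDIT4, MIF, CREBBP, RBX1 and ELOB. Fatty acid handling (adjusted p = 0.121) held FABP4 (-6.29 ± 1.45) and FABP5 (-4.61 ± 1.27), which also lead the venous-like cluster. Cattle 3 was far above the other cattle in both, and without it they were at -3.86 and -2.07. They missed the threshold in 4 and 10 of the settings fixed at the start. Mitochondrial genome transcripts (adjusted p = 0.181; ATP8, which overlaps ATP6, 3.01 ± 0.31), the 2 antigen presentation lists, complement, inflammatory response, TGF-beta and BMP signalling, heat shock, matrix, surfactant and cell cycle genes had adjusted p of at least 0.15. C1QA, C1QC and DCN were at free RNA levels.

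RN18S1 was higher in yak in the same cells (4.98 ± 0.58), where the lists that passed camera were lower. Of yak endothelial-like cells 41.4%, 26.0% and 32.6% came from clusters 5, 9 and 16, against 46.9%, 39.8% and 13.3% in cattle. The endothelial count was 885 without yak 1, 1394 without yak 2, 655 without yak 3, 1091 without cattle 2 and 1120 without cattle 3. It was 1379 with counts thinned to the smallest library, and 4 with the ribosomal RNA share as a covariate. FMO1, IFI47 and the HIF1A, EGLN1, KDR, EDN1 and VWF results stayed on the same side of the threshold in every alternative tried for them. Below the threshold, EDN1 (-0.69) and KDR (-0.12) changed direction in aerocyte-like cells alone, EDN1 also with the ribosomal RNA share as a covariate (-1.79), and HIF1A and VWF in several settings.

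In AT2-like cells 999 of 8637 genes differed between yak and cattle, 518 higher and 481 lower in yak. FMO1 was at 1332 ± 365 CPM in yak, 1379 ± 1236 in dzho and 0.397 ± 0.688 in cattle, where it had 3 UMIs (edgeR adjusted p = 0.00842). The adhesion molecule CDH2 rose by 5.08 ± 0.69 and RN18S1 by 4.21 ± 0.42. WFDC18 fell (-6.73 ± 1.58, adjusted p = 0.0452), with all 27 yak UMIs in yak 2 (without it none remained, adjusted p = 0.0801), and no UMI of SHISAL1 was found in yak (at least 26.2-fold lower), which was at 47.4 ± 19.6 CPM in dzho and 35.4 ± 10.2 in cattle. Of 17 surfactant and lamellar body genes 3 were higher, the phosphate transporter SLC34A2 (1.61 ± 0.31), CD36 (1.18 ± 0.24) and the transcription factor ETV5 (0.92 ± 0.27), while the surfactant protein SFTPD was lower (-0.84 ± 0.26; list adjusted p = 0.419). Adjusted over the list alone, 4 were higher and 2 lower.

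Of 59 oxidative phosphorylation genes 21 fell in AT2-like cells (33 adjusted over the list alone), such as NDUFV1 (-1.15 ± 0.27). Of 26 antioxidant genes 6 fell (10 adjusted over the list alone), such as PRDX5 (-2.17 ± 0.28), the extracellular dismutase SOD3 (-3.75 ± 0.56) and GPX1 (-1.93 ± 0.38). Ribosomal proteins (3 higher, 1 lower of 81; RPL15 -2.46 ± 0.33), glycolysis (HK1 higher, ALDOA, PGAM1 and LDHB lower), early response (0 of 23 members by edgeR), complement and cell cycle lists also passed as lower. The called complement and cell cycle members, such as C1QA and CDK1, were at free RNA levels. Adjusted over the list alone, 2 ribosomal protein genes were higher and 1 lower, 1 glycolysis gene higher and 4 lower. All 7 lists had adjusted p between 0.855 and 0.958 with an estimated correlation, and by fry antioxidant (0.0455) and complement genes (0.0363) passed. Of 34 hypoxia targets 4 were higher, including ANKRD37 (3.28 ± 0.60) and DDIT4 (2.12 ± 0.42), and 4 lower, including MIF (-2.37 ± 0.39; list adjusted p = 0.904; 5 and 4 adjusted over the list alone). EPAS1 was higher (1.27 ± 0.39, adjusted p = 0.0486), and the acyl-CoA synthetase ACSL1 was higher (2.08 ± 0.33). The AT2 count was 364 without yak 1, 616 without yak 2, 338 without yak 3, 534 without cattle 2 and 607 without cattle 3. It was 1528 with no low-count filter, and 15 with the ribosomal RNA share as a covariate. WFDC18 (without yak 1, adjusted p = 0.132) and EPAS1 (without yak 3, adjusted p = 0.158) lost the call in 8 and 9 of the settings fixed at the start, and FMO1 without cattle 3 (adjusted p = 0.0622).

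In fibroblast-like cells 1739 of 10466 genes differed, 875 higher and 864 lower in yak (599 and 1049 with no low-count filter, 239 and 134 without yak 1). FMO1 (341 ± 107 CPM in yak, 363 ± 294 in dzho, 0.124 ± 0.112 in cattle) and FMO2 (559 ± 525, 188 ± 200 and 0.346 ± 0.167) were again higher, as was RN18S1 (4.54 ± 0.58). The inflammatory cytokine IL6 (-5.89 ± 1.30) and the chitinase-like protein CHI3L1 (-5.59 ± 1.05) were lower, and XIST had no UMI in yak (at least 555-fold lower). The basement membrane collagens COL4A1 (2.43 ± 0.43) and COL4A2 (1.63 ± 0.44) rose and the protease inhibitor TIMP1 (-3.28 ± 0.87) fell, with 31 of 34 matrix genes not past the threshold (list adjusted p = 0.716; 2 higher and 1 lower adjusted over the list alone). Of 27 TGF-beta and BMP genes 4 rose, including the receptors BMPR2 (1.43 ± 0.29) and TGFBR3 (1.52 ± 0.31), and ENG fell (-1.96 ± 0.31; list adjusted p = 0.714; 4 and 2 adjusted over the list alone). PDE5A (1.46 ± 0.32) and the angiotensin receptor AGTR1 (1.39 ± 0.27) rose, while the chemokine CCL2 (-3.08 ± 0.47), the lipid droplet protein PLIN2 (-2.42 ± 0.42) and ANGPTL4 (-2.60 ± 0.28) fell.

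Of 59 oxidative phosphorylation genes 42 fell in fibroblast-like cells (55 adjusted over the list alone), such as NDUFS8 (-1.86 ± 0.29). Of 82 ribosomal protein genes 20 fell (53 adjusted over the list alone), such as RPL8 (-1.35 ± 0.32). Of 30 antioxidant genes 12 fell (14 adjusted over the list alone), such as MGST3 (-1.87 ± 0.26) and GPX4 (-2.29 ± 0.44). Of 29 interferon response genes 7 fell, such as IFI6 (-4.06 ± 0.81) and XAF1 (-2.39 ± 0.59), and 1 rose (8 and 1 adjusted over the list alone). These 4 lists passed camera, and had adjusted p of 0.855 or 0.909 with an estimated correlation. By fry the first and the antioxidant list passed (adjusted p = 0.0363 for both). Of yak fibroblast-like cells 95.2% came from cluster 11 and 4.78% from cluster 17, against 59.5% and 40.5% in cattle. RN18S1 was higher in yak where these lists were lower. The fibroblast count was 373 without yak 1, 663 without yak 2, 408 without yak 3, 370 without cattle 2, 321 without cattle 3 and 778 without both dzho 2 and cattle 2. It was 2737 with only yak and cattle in the fit, 883 with thinned counts, and 0 with the ribosomal RNA share as a covariate. CHI3L1 missed the threshold without yak 1 (adjusted p = 0.0595), IL6 in 5 and FMO2 in 6 of the settings fixed at the start.

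In macrophage-like cells 139 of 7655 genes differed, 58 higher and 81 lower in yak (66 and 61 without yak 1, 20 and 12 without yak 3). PLA2G7, which breaks down platelet-activating factor, was at 80.3 ± 39.3 CPM in yak, 47.8 ± 19.0 in dzho and 1.05 ± 0.605 in cattle (6.42 ± 0.65, edgeR adjusted p = 1.5e-04). The transferrin receptor TFR2 was at 35.7 ± 22.7, 28.8 ± 12.4 and 0.192 ± 0.332 CPM, a 96.8-fold ratio (95% counting interval 25.6 to 818). The lectins ASGR2 (33.9 ± 8.46 CPM in dzho, 156 ± 28.7 in cattle) and CLEC10A (23.6 ± 11.4 and 44.0 ± 13.6) had no UMI in yak, at least 73.8-fold and 21.5-fold lower. MIF (-2.14 ± 0.36), the complement receptor C3AR1 (-2.11 ± 0.36) and RPL15 (-3.14 ± 0.61) were lower, and the chemokine CXCL9 (3.30 ± 0.57) and RN18S1 (4.36 ± 0.56) higher. Oxidative phosphorylation (0 of 59 members by edgeR, 53 below 0) and antioxidant genes (0 of 27) passed camera as lower, and mitochondrial genome transcripts (ATP8, 2.89 ± 0.41, alone of 13) and heat shock genes (0 of 16) as higher. All 4 had adjusted p = 0.909 with an estimated correlation. The macrophage count was 404 without yak 2, 32 without yak 3, 83 without dzho 1, 61 without cattle 1, 72 without cattle 2, 53 without cattle 3 and 81 without both dzho 2 and cattle 2. It was 315 with DESeq2, 573 with no low-count filter, 87 with only yak and cattle in the fit, 224 with doublets kept, 67 with thinned counts, and 0 with the ribosomal RNA share as a covariate.

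In T cell-like cells 2802 of 11096 genes differed, 1326 higher and 1476 lower in yak. The DNA repair gene BRCA2 (2.41 ± 0.26) and ATP8 (2.36 ± 0.28) rose along with RN18S1 (4.32 ± 0.43), and the centromere protein CENPV (-4.23 ± 0.49) and RPL15 (-3.76 ± 0.58) fell. XIST had 1 UMI in yak and 3648 in cattle. RPL15 belongs to a family with many pseudogenes, and ribosomal RNA genes have many copies, so how reads were divided among the copies is uncertain for these. Of 17 HIF regulators 5 rose, including ARNT (1.40 ± 0.34), HIF1AN (1.61 ± 0.42) and the acetyltransferases CREBBP (1.26 ± 0.34) and EP300, and 1 fell (list adjusted p = 0.3; the same counts adjusted over the list alone). By fry this list passed as higher (adjusted p = 0.0385) and complement as lower (0.0363, against 0.0534 by camera), but with an estimated correlation they had adjusted p of 0.909 and 0.855. Of 13 complement genes 6 fell (8 adjusted over the list alone), and the 4 with the smallest p were at free RNA levels. Among heat shock genes HSPH1 (1.73 ± 0.45), HSPA5 (1.49 ± 0.40) and BAG3 (1.22 ± 0.33) rose and 2 fell (list adjusted p = 0.151; 4 and 2 adjusted over the list alone). Of 33 interferon genes 8 fell, such as IFI44 (-1.95 ± 0.47; list adjusted p = 0.182; 8 adjusted over the list alone). MYC (-1.21 ± 0.21) and the proteasome subunits PSMB10 (-2.10 ± 0.30) and PSMB9 (-1.34 ± 0.27) fell.

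Of 59 oxidative phosphorylation genes 27 fell in T cell-like cells (33 adjusted over the list alone), such as COX7B (-1.51 ± 0.32). Of 29 antioxidant genes 11 fell and TXN rose (1.21 ± 0.29), with the same counts adjusted over the list alone. Both lists passed camera, as did the matrix list, whose 4 called members, such as DCN and LUM, were at free RNA levels. Each had adjusted p = 0.909 with an estimated correlation. The T cell count was 868 without yak 1, 551 without yak 3, 4373 without dzho 2, 1203 without cattle 1, 1078 without cattle 2 and 867 without cattle 3. It was 4305 with only yak and cattle in the fit, and 18 with the ribosomal RNA share as a covariate.

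Over the 12 tested classes yak and cattle differed in 13546 of 103204 gene tests, 6574 higher and 6972 lower in yak, which involved 6419 distinct genes. Of these, 3269 were called in 1 class, 324 in at least 6 classes, and 4 in all 12, namely ATP8, LOC514457, SNRPD1 and XIST, which were singled out after their values were seen. In the other classes the largest changes by the rule were the dynein chain DYNC1I1 in AT1-like cells (no UMI in cattle, at least 137-fold higher), the peptidase GGT5 in lymphatic endothelial-like cells (6.23 ± 0.92) and the IgE receptor FCER2 in plasma-like cells (3.44 ± 0.43). They were FMO1 in secretory-like cells (5.13 ± 0.56) and RN18S1 in B cell-like (4.64 ± 0.40), NK-like (4.32 ± 0.39) and proliferating-like cells (5.01 ± 0.64), and XIST as the largest decrease in each. In proliferating-like cells RN18S1 missed the threshold without yak 1, yak 3, cattle 1, cattle 2 or cattle 3 (adjusted p between 0.0585 and 0.119). Counts were 1706 in B cell-like, 1663 in lymphatic endothelial-like, 1406 in AT1-like, 727 in NK-like, 111 in plasma-like, 36 in proliferating-like and 22 in secretory-like cells. By edgeR an unadjusted p under 0.05 was reached by 1140 of 6438 genes in plasma-like, 1620 of 8835 in proliferating-like and 1256 of 7024 in secretory-like cells. The total of called tests was 4930 without yak 1, 3869 without yak 3, 8484 without cattle 1, 5439 without cattle 2 and 5584 without cattle 3. It was 21041 with only yak and cattle in the fit, and 84 with the ribosomal RNA share as a covariate.

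**Figure D3:**
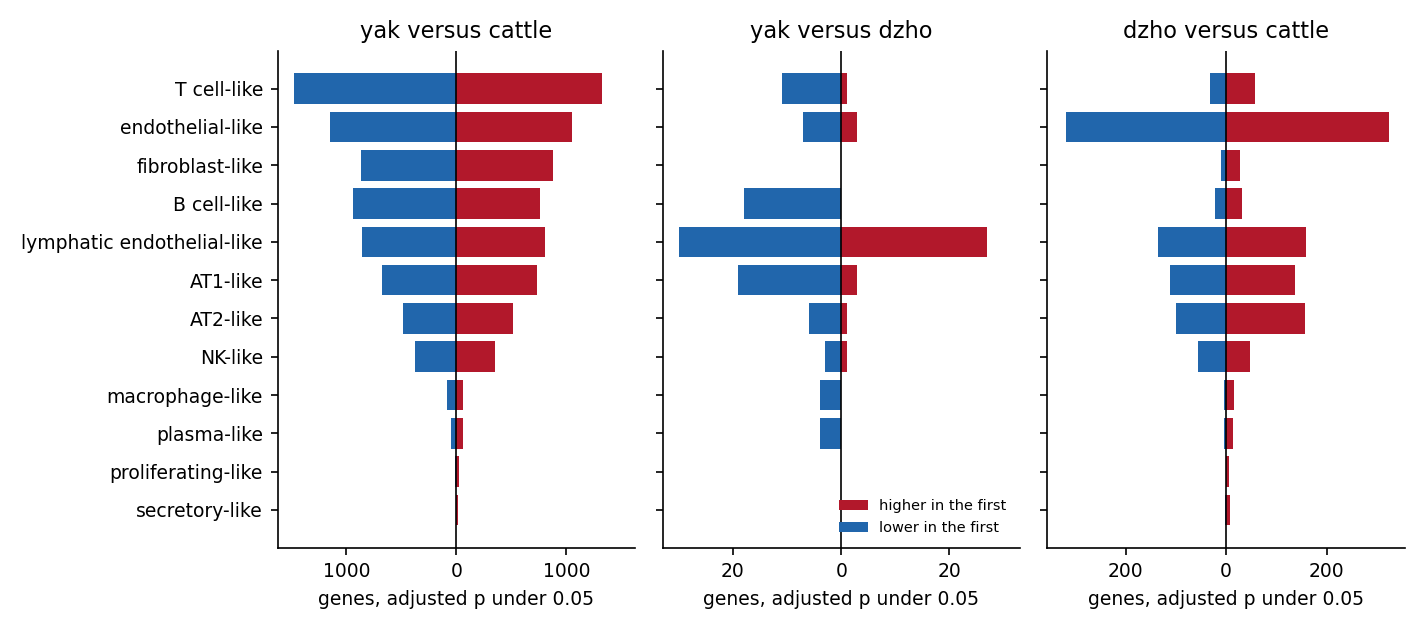
Number of genes past the threshold (adjusted p under 0.05) in each tested cell class, drawn to the right where higher and to the left where lower in the first group named, for yak against cattle, yak against dzho and dzho against cattle. Yak against cattle reached 2802 genes in T cell-like cells, while yak against dzho reached at most 57, in lymphatic endothelial-like cells.

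Between yak and dzho, 138 of the gene tests passed, 36 higher and 102 lower in yak. In endothelial-like cells (10 genes) the hormone STC1 was at 86.9 ± 34.0 CPM in yak and 10.7 ± 4.87 in dzho (3.27 ± 0.40, edgeR adjusted p = 0.00685), and at 70.1 ± 15.2 in cattle. GUCY1A1 was at 151 ± 25.5, 49.3 ± 19.2 and 41.1 ± 3.97 CPM in yak, dzho and cattle (yak against dzho 1.70 ± 0.28, adjusted p = 0.0490). IFI47 was 83.1-fold lower in yak by the ratio of CPM (95% counting interval 28.3 to 404; adjusted p = 8.2e-05) and STAP2 at least 11.04-fold lower (adjusted p = 0.0490). In lymphatic endothelial-like cells (57 genes) RASEF (2.19 ± 0.34) and the synaptic scaffold HOMER1 (1.82 ± 0.32) were higher in yak, and the sodium pump regulator FXYD6 (-3.21 ± 0.58) and the transcription factor MYC (-2.55 ± 0.34) lower. By edgeR no gene passed in fibroblast-like, proliferating-like or secretory-like cells, where 1571, 1256 and 347 had an unadjusted p under 0.05. The count was 28 without yak 3 (4 higher and 24 lower), 90 without dzho 2 (8 and 82) and 1191 without dzho 3 (438 and 753). It was 808 with DESeq2 (39.4% higher in yak against 26.1% with edgeR), and 1772 with no low-count filter. GUCY1A1 missed the threshold in 11 and STAP2 in 8 of the settings fixed at the start, and STC1 without dzho 2 (adjusted p = 0.0965) or with doublets kept (0.086). MYC missed it without yak 3 (0.0998), HOMER1 without yak 1 (0.0774), yak 3 (0.149) or dzho 2 (0.0714), and FXYD6 in 5 of these settings (0.182 without yak 3).

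Between dzho and cattle, 1781 gene tests passed, 984 higher and 797 lower in dzho (562 and 730 without cattle 1). In endothelial-like cells (641 genes) FMO1 (11.28 ± 0.66, edgeR adjusted p = 1.6e-06) and RN18S1 (4.42 ± 0.56) were the largest increases. XIST (no UMI in dzho, at least 968-fold lower) and the transcription factor MEOX1 (-5.61 ± 1.05, adjusted p = 0.0261) were the largest decreases. MEOX1 also leads the venous-like cluster, which held 0.525% of endothelial-like cells in dzho 2. Lymphatic endothelial-like cells had 295, AT2-like cells 257 and AT1-like cells 248 such genes, and macrophage-like cells 20. The count was 1117 without yak 3, 1022 without dzho 1, 8748 without dzho 2, 716 without dzho 3, 700 without cattle 2, 591 without cattle 3 and 4469 without both dzho 2 and cattle 2. It was 3491 with DESeq2, 6238 with no low-count filter, 962 with only dzho and cattle in the fit, 1108 with thinned counts, and 97 with the ribosomal RNA share as a covariate. MEOX1 missed the threshold without dzho 1 (adjusted p = 0.0581), cattle 2 (0.0512) or cattle 3 (0.059), with only dzho and cattle in the fit (0.0665), and with doublets kept (0.0607).

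Because dzho are hybrids, the place of each dzho between cattle (0) and yak (1) was computed over the genes called between yak and cattle. In endothelial-like cells the median gene lay at 0.572 in dzho 1, 0.418 in dzho 2 and 0.950 in dzho 3, a mean of 0.647 ± 0.274 (SD, n = 3, no test). Class means ran from 0.462 ± 0.219 in lymphatic endothelial-like to 0.722 ± 0.0923 in secretory-like cells, and were 0.596 ± 0.366 in T cell-like, 0.643 ± 0.193 in AT2-like, 0.486 ± 0.112 in fibroblast-like and 0.570 ± 0.0888 in macrophage-like cells. Dzho 2 was the lowest of the 3 dzho in all classes but the secretory-like. When the 3 groups were tested together, 1644 genes differed in endothelial-like cells, 1151 in T cell-like, 708 in fibroblast-like, 606 in AT2-like and 86 in macrophage-like cells. The number of genes that differ among the 3 groups, endothelial-like, was 778 without yak 1, 1040 without yak 2, 431 without yak 3, 1022 without cattle 1, 456 without cattle 2, 430 without cattle 3 and 1019 without both dzho 2 and cattle 2. It was 905 with thinned counts and 14 with the ribosomal RNA share as a covariate.

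**Figure D4:**
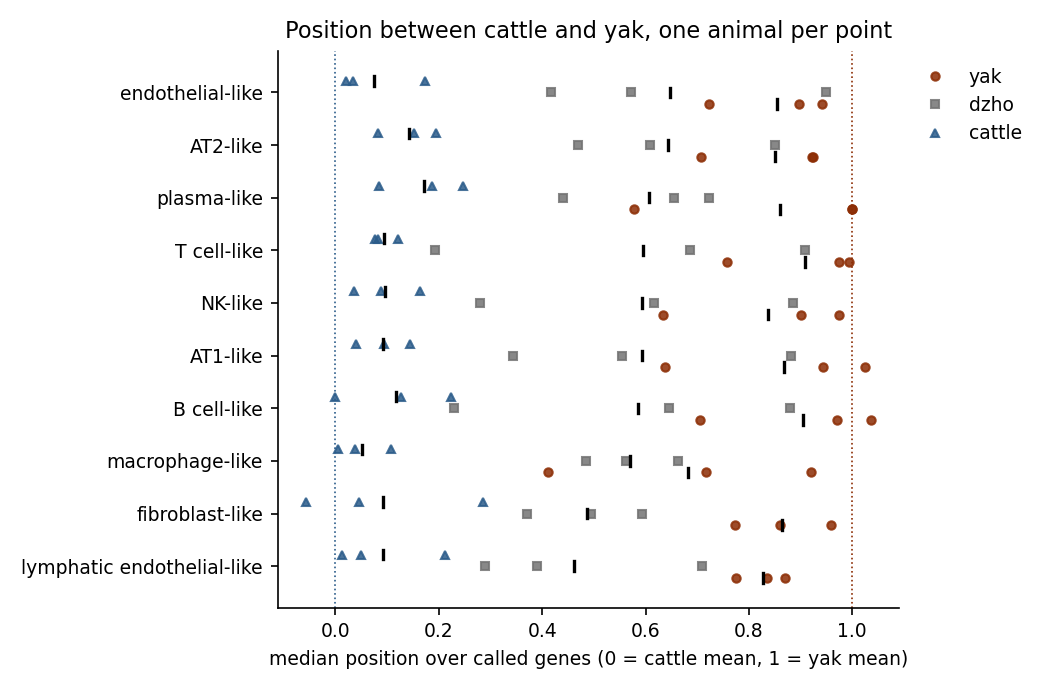
Place of each dzho library between the cattle mean (0) and the yak mean (1), as the median over genes called between yak and cattle, by cell class, shown beside yak and cattle libraries each placed by a fit that left it out, for the classes where all of these could be placed. In endothelial-like cells dzho 1, 2 and 3 lay at 0.572, 0.418 and 0.950.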

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

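Of the patterns weighed below, the tests of RNA state over all 9 libraries and with a library left out, of reads lost on the cattle genome, of a cattle library under the dzho label, and of RNA state and subtypes on the lists were chosen after the result was seen. Thinning for the dzho position was added after the data were seen, but before its own result.

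More genes differed between yak and cattle (13546 tests over 12 classes) than between yak and dzho (138). The biological explanation is the difference between the species, and a technical one is the RNA state of the libraries, tracked by RN18S1. Across libraries of the same group, the RN18S1 share explained the called endothelial-like genes beyond chance with all 9 libraries (exact permutation p = 0.0231), which fits this as a part of the pattern. The median explained share was 86.5%. Over the 12 classes it ran from 17.7% (macrophage-like) to 110% (T cell-like), so it is not a share of variance. Without yak 1 (p = 0.0556, share 86.6%), dzho 1 (0.0694, 91.8%), dzho 2 (0.0694, 71.0%), dzho 3 (0.0833, 47.5%) or cattle 1 (0.0833, 101%) the test missed the threshold, with fewer permutations. Yak and cattle libraries alone could not tell (exact permutation p = 0.167). There the share was 38.4%, and over the classes it ran from 5.32% (macrophage-like) to 58.3% (fibroblast-like). With all 9 libraries p was under 0.05 in 8 of 12 classes, and without dzho 2 in 1. Reads of yak lost on the cattle genome stay open: 51.5% of calls were lower in yak, but the scaling centres the fold changes, so this share decides nothing. Sex, read from XIST, could not be told apart from species: the mean dzho position lay below all 3 held-out yak in 8 of the 10 classes with values for all 3, but cattle alone had XIST. The dzho were placed by the fit of all libraries and each held-out yak by a fit without it, so these positions rest on unlike fits.

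Dzho 2 lay closer to cattle than dzho 1 and dzho 3 in endothelial-like cells (0.418 against 0.572 and 0.950). A female cattle library under its label is excluded, since dzho 2 had 1 XIST UMI where each cattle library had at least 19412. XIST cannot tell whether it came from male cattle, which would lack XIST too. The depth of dzho 2 is excluded, since thinning moved its position by 0.0285. Its RNA state could not be told from a difference between the animals: after a correction for the RN18S1 share the range of the 3 dzho shrank by 28.4%, from 0.532 to 0.381.

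The lists of oxidative phosphorylation (39 of 59 genes past the threshold) and ribosomal protein genes (37 of 82) were lower in yak than in cattle endothelial-like cells by camera, but not with an estimated correlation (adjusted p = 0.909 for both). A species difference is the biological explanation, and the technical ones are RNA state and a different mix of endothelial subtypes. Within groups, the oxidative phosphorylation mean followed the RN18S1 share (exact permutation p = 0.0139, at most 0.0417 with any library left out), which fits RNA state, while the ribosomal protein mean could not tell (exact permutation p = 0.0694). The dzho with a higher RN18S1 share also lay nearer to yak in these cells, so a difference between the dzho animals could add to this trend too. The mix of subtypes is excluded as the whole cause for oxidative phosphorylation, where aerocyte-like cells alone kept 105% of the difference. For ribosomal proteins they kept 71.9%, which cannot tell. The other subtypes were not tested alone.

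Other splits of the same libraries were tested in the same way. With 10 splits a share under 0.05 cannot be reached, so the pairs of groups could not be told from chance by this test. The real split gave the most calls, 1 of 10, for yak against cattle (13546, highest other 1), dzho against cattle (1781, highest other 35), and yak against cattle in endothelial-like (2196, highest other 0), AT2-like (999, 0), fibroblast-like (1739, 0), macrophage-like (139, 1) and T cell-like cells (2802, 0). For yak against dzho 2 of 10 splits gave as many (138, highest other 514, which set yak 1, yak 3 and dzho 3 against the others), and for the lists 8 of 10 did (24, highest other 37). For the 3 groups tested together in endothelial-like cells, 2 of 100 splits gave as many (1644, highest other 2110). That share is under 0.05, so chance is unlikely for this count but not excluded. The 5 splits with over 3 calls, the real one included, all kept the 3 cattle together. The one with 2110 set yak 1, yak 3 and dzho 3 against yak 2, dzho 1 and dzho 2, so the count sets cattle apart from the others and does not separate yak from dzho.

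Some genes passed the test in opposite directions in different cell classes, and these differences between classes were not tested. Log2 fold changes of yak against cattle were -6.33 in endothelial-like and 2.74 in fibroblast-like cells for NTRK2, and 1.91 in endothelial-like, 2.12 in AT2-like and -0.91 in T cell-like cells for DDIT4. For TXN they were -1.81 in fibroblast-like and 1.21 in T cell-like cells, and for SMAD7 -1.51 in AT2-like, at the level of free RNA, and 1.30 in T cell-like cells. TGFB2 was at 1.36 in endothelial-like, -3.02 in AT2-like, at the level of free RNA, and 0.96 in fibroblast-like cells.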

How the results depend on the processing

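Of 315 named gene results, 125 kept their side of the threshold, and their direction where past it, in every alternative fixed at the start. Of their 5862 values there, 5042 stayed the same, 816 were no longer past the threshold, 4 became so, and no result past the threshold turned its direction. Leaving out yak 3 moved the most (166 of 315 no longer past it) and RLE scaling none, while the ribosomal RNA share as a covariate, added later, left 29 of 315 the same. That share differs between the groups, so the covariate takes up part of the difference between them by construction. In simulated data 19.4% of 2-fold changes were found in endothelial-like cells, and 37.9% of 4-fold changes in macrophage-like cells, the lowest of the 5 main classes. The simulated endothelial-like counts gave 72 calls, against 2196 in the real ones. The adjustment was therefore stricter in the simulation, and these shares need not hold for the real counts. Counts with a library left out rest on 2 animals in its group.

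No class share passed in any alternative. Over 15 classes a class alone could not pass the exact test, also with a library left out, so this does not show that the shares are alike. The dzho position in endothelial-like cells ran from 0.473 (without dzho 3) to 0.788 (without dzho 2), within the spread of the animals. With each library left out in turn, counts ran from 3869 to 19530 for yak against cattle, 28 to 1191 for yak against dzho, 591 to 8748 for dzho against cattle, and for yak against cattle from 655 to 2831 in endothelial-like, 338 to 1337 in AT2-like, 321 to 2493 in fibroblast-like, 32 to 404 in macrophage-like and 551 to 4373 in T cell-like cells. They ran from 430 to 2338 for the 3 groups tested together in endothelial-like cells, from 21 to 32 for the list tests, and from 0 to 1 for endothelial subtypes. Why single animals moved the counts was not tested.

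Other counts moved by over 1.5 times as follows, and the cause was not tested. With only the compared groups in the fit, yak against cattle gave 21041, dzho against cattle 962, fibroblast-like cells 2737, macrophage-like 87 and T cell-like 4305. With DESeq2, yak against dzho gave 808, dzho against cattle 3491 and macrophage-like cells 315. With no low-count filter, yak against dzho gave 1772, dzho against cattle 6238, AT2-like cells 1528, macrophage-like 573 and the list tests 48. With thinned counts, dzho against cattle gave 1108, endothelial-like cells 1379, fibroblast-like 883, macrophage-like 67 and the 3 groups together 905. With doublets kept, macrophage-like cells gave 224, with the stricter cell filter 1 endothelial subtype passed, and aerocyte-like cells alone gave 1035 genes. Without dzho 2 and cattle 2, dzho against cattle gave 4469, fibroblast-like cells 778, macrophage-like 81 and the 3 groups together 1019. With the ribosomal RNA share as a covariate, yak against cattle gave 84, dzho against cattle 97, endothelial-like cells 4, AT2-like 15, fibroblast-like 0, macrophage-like 0, T cell-like 18, the 3 groups together 14 and the list tests 37. An estimated correlation left 0 list tests and fry 7.

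With the replicate number as a block, yak against dzho gave 331 genes, and no other count moved by over 1.5 times. Of 108 correlations between libraries of the same number, 32 were above 0.1 (from -0.405 to 0.455), and 3 of 9 endothelial-like libraries correlated best with their own number. No clear pairing by number was seen, which does not exclude one.

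NOS3 in endothelial-like cells turned from a log2 fold change of 0.42 to -2.38 in aerocyte-like cells alone (adjusted p = 0.0402). The ribosomal RNA share as a covariate turned the genes below, none past the threshold, and the cause was not tested. In endothelial-like cells these were APLNR 0.11, PRDX1 0.15, PRDX2 0.21, SOD1 0.11, GSTO1 0.0702, PCNA 0.34, PLIN2 0.30, LDHB 0.22, PGAM1 0.18, PGK1 1.23, RBX1 0.11, ELOB 0.72, CREBBP -0.0564, EP300 -0.73, COX7B 0.0143, ATP5MC2 0.63, UQCRFS1 0.54, RPL10 0.67, CTSH 1.71, DDAH2 0.091. In AT2-like cells these were PSMB10 2.08, CTSS 1.01, GPX1 1.44, MCM4 0.60, ALDOA 0.45, PGAM1 0.20, LDHB 1.89, HSPH1 -1.57, ELOC 0.0848, EPAS1 -0.93, NDUFV2 0.59, SLC34A2 -0.18, SFTPD 0.34. In fibroblast-like cells these were COL4A2 -0.69, RBX1 0.0842, SIRT1 -0.27, CXCL9 -1.21. In T cell-like cells these were ACVRL1 0.86, EFNB2 -3.05, ERG 3.87, PRDX3 0.79, PRDX5 0.39, MCM5 0.45, TIMP1 0.21, EGR1 -0.041, ECHS1 0.89, LDHB 0.79, HK2 -2.31, HSPH1 -2.60, HSPA5 -1.88, BAG3 -1.49, EP300 -1.31, CREBBP -1.31, KDM3A -0.32, P4HA1 -0.33, PTGS2 -0.0643, NDUFB3 1.11, ATP5MC1 0.52, SFTPC 0.88, SFTPD 1.57, SFTPA1 0.42, TGFB1 -0.26, ID1 0.95, SMAD7 -1.80, CAV1 1.35, CALCRL 1.16.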

Other observations

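Among the clusters that stayed unnamed, the largest difference was in cluster 1, whose leading genes TRGC3, CCL5, PRF1, CTSW and KLRC1 are known from gamma delta and cytotoxic lymphocytes. It held 27.0% ± 8.08 of all cells in yak, 9.62% ± 2.96 in dzho and 3.63% ± 0.411 in cattle (SD, n = 3; exact permutation p = 0.00357, adjusted p = 0.0929 over 26 classes and clusters), which missed the threshold. This unadjusted p is the smallest the test can give, so with 26 classes and clusters a cluster alone could not have passed. Cluster 12, led by the matrix genes NDNF, ELN and PRG4, was at 1.71% ± 0.953, 2.12% ± 0.722 and 5.13% ± 1.72 (exact p = 0.025, adjusted p = 0.17). Cluster 15, led by CCL8, FCER1A and BOLA-DQB, known from dendritic cells among others, was at 2.17% ± 0.609, 1.43% ± 0.0949 and 3.63% ± 1.22 (exact p = 0.0393, adjusted p = 0.17). Cluster 7, led by the defensins TAP and DEFB4A and by MMP12, was at 3.75% ± 4.15, 8.79% ± 3.30 and 2.03% ± 1.13 (exact p = 0.0714), and cluster 8, led by IL1B and EREG, at 6.35% ± 3.58, 1.63% ± 0.221 and 4.25% ± 0.636 (exact p = 0.111).

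Within the immune compartment, T cell-like cells were at 56.8% ± 4.37 in yak, 47.2% ± 2.40 in dzho and 36.6% ± 11.7 in cattle (exact permutation p = 0.00714, adjusted p = 0.1) and macrophage-like cells at 12.6% ± 4.77, 21.4% ± 3.32 and 36.1% ± 18.6 (exact p = 0.0464). Immune classes together were at 73.4% ± 9.83, 57.0% ± 24.3 and 36.3% ± 11.9 of named cells without the proliferating-like class (exact p = 0.111). Placed by fits that left each of them out, the yak lay at 0.897, 0.723 and 0.942 in endothelial-like cells and the cattle at 0.172, 0.0339 and 0.0197, so 0 and 1 are the means of the fitted animals and not where a new animal falls.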
